A study of Mus musculus with 30 samples.

How the data were processed

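Liver RNA of 30 C57BL/6J mice was measured, 16 raised conventionally with a gut microbiota and 14 raised germfree, after 11 weeks on a high-fat diet and 10 h without food. Biotin-labelled cRNA from each liver was hybridized to an Illumina single-colour mouse array, so that each array is the sample of 1 animal. Microbial status was the only factor in the labels. No batch, chip, cage or order of processing was given in the sources used here.

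The deposited signal table held, per the file headers, the mean bead intensity of each probe on each array without normalization, and GenomeStudio was named in the submitters' processing notes without a version. Per the file headers, the same table held a detection p-value for each probe and array, which compares the probe with the negative control beads. The authors also deposited a value table of the same arrays, which held linear intensity after quantile normalization, a step and a wider set of samples named in a comment of the file headers. Each array kept its order of probes in that table (rank correlation 1 with its own raw signal), every array had nearly the same distribution with a median of 57.96, and no log transform or group centring had been applied. The signal table also held 33 arrays without a sample in the labels, whose signals entered no fit here. Whether they belong to that wider set, and so shaped the authors' values used as an alternative, was not established.

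Signals were background corrected with normexp, with the background estimated from the detection p-values, offset by 16, quantile normalized between the 30 arrays and log2 transformed (neqc in limma 3.58.1, R 4.3.3). A probe was kept when its detection p-value was under 0.05 on at least 7 arrays, which left 10525 of 24613 probes. Gene names came from the platform annotation, which listed 20985 probes, 20984 of them with 1 gene symbol and 1 with several. The other 3628 probes are unnamed here and were tested under their own identifier. Symbols were updated through gene identifiers (20968 probes) or transcript accessions (8 probes), which renamed 7, and 9 probes kept the name in the annotation. For a gene with several probes the probe with the highest mean was used. Among the 90 changed genes with further probes, 16 had a further probe with the opposite sign. In all, 9084 genes were tested, 7839 of them named.

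Germfree and conventional livers were compared with limma (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 changes are germfree minus conventional, and their errors are the moderated standard errors. For 33 gene lists, fixed before the data were examined, limma's rotation test fry asked whether the members moved on balance in a single direction, with adjustment over the 31 lists that had at least 5 tested members. The test was also run as camera with a preset correlation of 0.01 and with a correlation estimated per list. Named genes are the 12 largest rises and the 12 largest falls among named genes past the threshold, the up to 4 members of each list with the smallest adjusted p, and a fixed set of bile acid, sterol, lipid, glucose and immune genes. Irs2 had no named probe, and Nr0b2, Srebf1 and Cpt1a were removed by the filter, so these were not analysed here. Some other genes of the fixed set are not reported here.

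The procedure was tested on simulated data with the sizes, means and spread of this comparison of germfree against conventional liver over 9084 genes. It recovered 31.3% of genes changed by 0.25 on the log2 scale, 91.0% of those changed by 0.5 and 98.5% of those changed by 1, and called 2 of 8884 unchanged genes. With no effect, fry gave an unadjusted p under 0.05 for 10 of 200 sets. Genes were simulated independently and sets drawn at random, so this does not show how fry behaves on correlated lists. The estimated correlation was 0.40 in the cholesterol synthesis list and 0.47 in the Kupffer cell and macrophage list.

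The alternatives were no background correction, the authors' normalized values, median scaling, cyclic loess, no filter, a filter at a detection p of 0.01 on 14 arrays, the mean of a gene's probes, every probe on its own, array weights, an intensity trend with robust variance, the detected share as a covariate, the replicate number as a block, stricter thresholds, both forms of camera and each array left out in turn. Added after the data were seen were the main axis of variation within groups as a covariate, the parts on either side of 0 on that axis, median scaling over the probes detected on all arrays, the 28 arrays of the block without the block, and the arrays with a mean signal under 160 left out. Correlations, and differences in array quality, were tested with 100000 permutations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.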

Results

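The livers of 14 germfree and 16 conventional mice were compared on single-colour arrays after a high-fat diet. The design asks how the absence of a gut microbiota alters hepatic gene expression, with cholesterol metabolism named as a point of interest. The share of probes detected was 38.4% ± 1.94 (SD, n = 16) in conventional and 38.4% ± 1.60 (SD, n = 14) in germfree livers (permutation p = 0.924, two-sided). Mean raw signal was 245 ± 67.4 (SD, n = 16) and 247 ± 73.6 (SD, n = 14) intensity units (permutation p = 0.937, two-sided). It ran from 85.5 to 359 between arrays, and the number of arrays limits the precision. Normalized arrays correlated at 0.963 to 0.991 and none were identical.

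Genes of cholesterol synthesis rose together in germfree liver. Squalene epoxidase, Sqle, had the largest rise of any named gene by the probe used, 3.22-fold (log2 change 1.69 ± 0.29, SE, 14 against 16 livers), while its other probe had a log2 change of 0.98. Constitutive androstane receptor target Cyp2b10 had the largest fall, 4.54-fold (log2 change -2.18 ± 0.28). It was detected in 11 of 14 germfree livers, so some germfree values were not above background and the size is approximate. Of 28 tested genes of the glutathione list 5 fell, and of 12 Kupffer cell and macrophage markers 4 fell; the list shifts had adjusted p = 0.0816 and 0.179 with an estimated correlation (camera in limma). Among genes of fatty acid and triglyceride synthesis, Pparg, Thrsp and Scd1 fell and Fads2 rose, and the list did not pass. Of 9084 genes tested with limma, 590 passed an adjusted p of 0.05, 341 higher and 249 lower in germfree liver, and 1703 had an unadjusted p under 0.05, against 454.2 by chance. Most changes were small. The median size among the 590 was 1.30-fold, 113 changed at least 1.5-fold (59 higher and 54 lower), and 13 rose and 14 fell at least 2-fold. Among named genes, 300 rose and 214 fell.

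Of the 18 tested genes of cholesterol synthesis and LDL uptake, 14 rose, none fell and 4 did not pass. Adjusted over the list alone, 17 rose. The median log2 change was 0.66 (quartiles 0.40 and 0.97), and the list passed limma's fry test (adjusted p = 1.03e-05), also with a correlation estimated for the list (camera in limma, adjusted p = 0.0231 with an estimated correlation). Beside Sqle, the methylsterol oxidase Msmo1 rose by 1.30 ± 0.18 on the log2 scale, HMG-CoA synthase Hmgcs1 by 1.14 ± 0.18 and lanosterol demethylase Cyp51 by 1.07 ± 0.16. Dhcr7, the last enzyme toward cholesterol, rose by 0.74 ± 0.11 and Hsd17b7 by 0.74 ± 0.11. In each of these genes all 14 germfree livers lay above the conventional mean. Insig1, which retains the sterol-sensing complex in the endoplasmic reticulum, rose by 0.57 ± 0.10 (limma, adjusted p = 0.000424). Its other probe had a log2 change of 0.31. Srebf2, the transcription factor of the pathway, did not pass (log2 change 0.36 ± 0.14, limma adjusted p = 0.120).

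**Figure D1:**
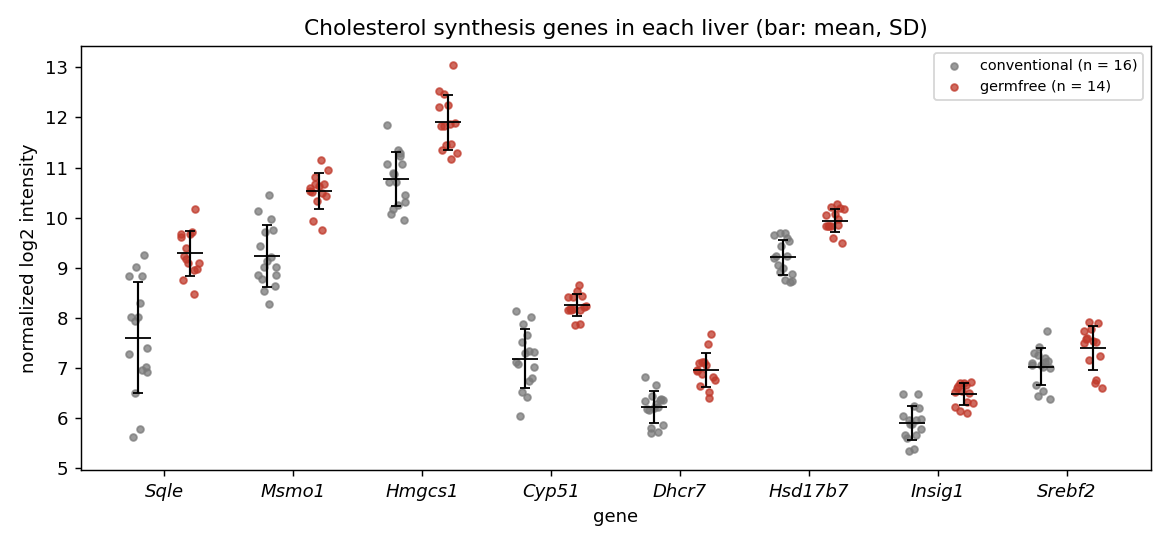
Normalized log2 intensity of 8 genes of the cholesterol synthesis list in each of 16 conventional and 14 germfree livers; points are livers and bars the mean and SD. Sqle averaged 7.60 in conventional and 9.29 in germfree livers, and Srebf2 was the only gene of the 8 that did not pass.

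Among genes that handle cholesterol once made, the canalicular half-transporters Abcg5 and Abcg8, which export sterols into bile, rose by 0.30 ± 0.08 and 0.48 ± 0.14 on the log2 scale (limma, adjusted p = 0.0188 and 0.0269). Abcg8 was lost without germfree liver 7 or 9 (limma, adjusted p = 0.0515 and 0.0526). The bile acid receptor Nr1h4 (FXR) fell, with a log2 change of -0.33 ± 0.06 and all 14 germfree livers below the conventional mean (limma, adjusted p = 0.000379). The organic anion transporter Slco1a4 and the FGF co-receptor Klb rose by 0.65 ± 0.15 and 0.43 ± 0.12. Slco1a4 was detected in 9 of 16 conventional livers, so the size of its rise is approximate. Over the 18 tested genes of bile acid and sterol transport and sensing, 4 rose, 1 fell and 13 did not pass, and adjusted over the list alone 5 rose and 1 fell; the list did not pass (fry in limma, adjusted p = 0.142). Abcb11, Abcb4 and Slc10a1 were not past the threshold, with log2 changes of -0.23, 0.25 and 0.05. Abca1 was detected in 6 of 16 conventional and 2 of 14 germfree livers, so a change in it could not be assessed.

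Of 14 genes of bile acid synthesis and conjugation, 1 fell and 13 did not pass, and adjusted over the list alone the count was also 1 (fry in limma, adjusted p = 0.462). The gene that fell was Cyp8b1, the 12-alpha-hydroxylase that sets the share of cholic acid, at -0.56 ± 0.15 (limma, adjusted p = 0.0157). It did not pass with the replicate number as a block or after median scaling. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, varied widely between livers (SD 1.25 and 0.90 in conventional and germfree) and did not pass (log2 change 0.48 ± 0.37, limma adjusted p = 0.543). Cyp27a1 and Cyp7b1 had log2 changes of 0.17 ± 0.07 and 0.22 ± 0.19 and did not pass. Of 19 genes of lipoprotein assembly, Apom alone rose (log2 change 0.48 ± 0.08), 18 did not pass and adjusted over the list alone 1 rose. That list's median was 0.01 and its test pointed up, while its mean was below 0 (fry in limma, adjusted p = 0.291).

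Lipogenic genes moved in opposite directions. Of 23 genes of fatty acid and triglyceride synthesis, 3 rose, 4 fell and 16 did not pass, and adjusted over the list alone 6 rose and 6 fell. Pparg fell, with a log2 change of -1.17 ± 0.16, as did Thrsp (-1.08 ± 0.24), Scd1, the main hepatic stearoyl-CoA desaturase (-0.83 ± 0.20), and Pklr (-0.65 ± 0.16). Pparg was detected in 12 of 14 germfree livers, so the size of its fall is approximate. The polyunsaturated fatty acid desaturase Fads2 rose by 0.71 ± 0.14. Fasn and Acaca had log2 changes of -0.31 ± 0.16 and -0.35 ± 0.12 and did not pass. The list as a whole did not pass; its median was above 0 and its mean and test were below (fry in limma, adjusted p = 0.870). Of 28 genes of fatty acid oxidation and PPARA targets, 1 rose (Cyp4a10, 0.49 ± 0.15), 1 fell (Acaa1b, -0.48 ± 0.08) and 26 did not pass, the same counts as adjusted over the list alone. Cyp4a10 was lost in 19 of 30 fits that left out 1 liver. The list's median and mean were above 0 and its test pointed down (fry in limma, adjusted p = 0.870). Ppara (0.29 ± 0.16), Cyp4a14 (0.56 ± 0.24) and Fgf21 (0.26 ± 0.30) did not pass.

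**Figure D2:**
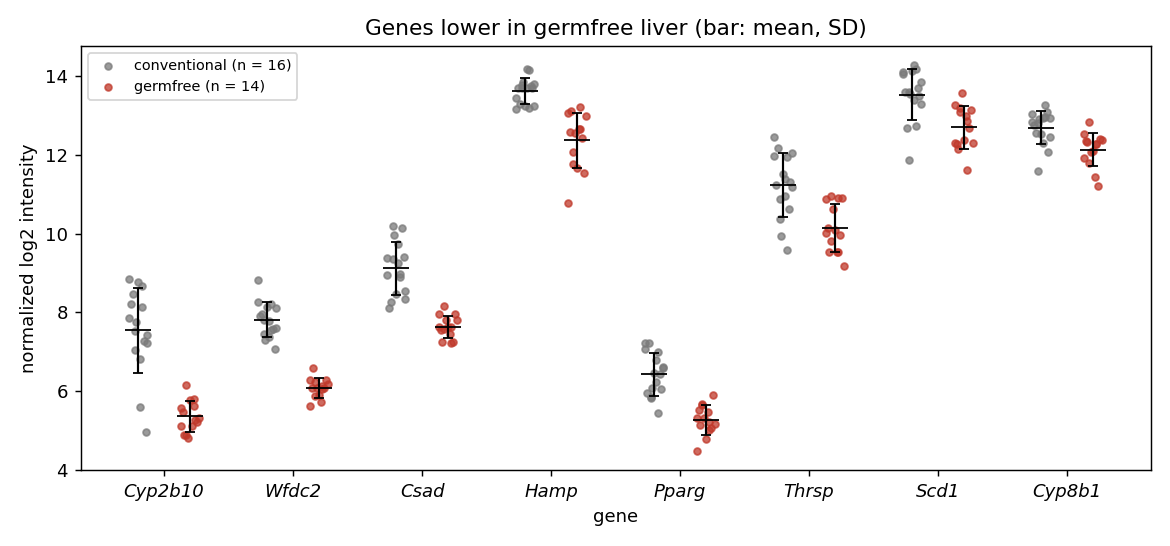
Normalized log2 intensity of 8 genes that fell in germfree liver, in each of 16 conventional and 14 germfree livers; points are livers and bars the mean and SD. Cyp2b10 averaged 7.54 in conventional and 5.35 in germfree livers, and Wfdc2 averaged 7.81 and 6.08.

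The insulin-repressed binding proteins Igfbp1 and Igfbp2 rose by 1.37 ± 0.32 and 1.23 ± 0.16 on the log2 scale (limma, adjusted p = 0.00574 and 3.18e-06). Glycogen phosphorylase Pygl (-0.41 ± 0.09) and fructose bisphosphatase Fbp1 (-0.34 ± 0.06) fell. Glucose-6-phosphatase, G6pc, lay just outside the threshold (0.66 ± 0.21, limma adjusted p = 0.0520) and Pck1 did not pass (0.32 ± 0.29). Of 21 genes of gluconeogenesis, glycolysis and insulin signalling, 3 rose, 3 fell and 15 did not pass. Beside Igfbp1 and Igfbp2, the member that rose was Ppargc1a (0.71 ± 0.18, limma adjusted p = 0.0124). Adjusted over the list alone 5 rose and 4 fell. The list's median was below 0, while its mean and test were above (fry in limma, adjusted p = 0.796). Of 24 genes of amino acid, urea cycle and one-carbon metabolism, 1 rose (Bhmt2, 0.23 ± 0.06), also adjusted over the list alone (fry in limma, adjusted p = 0.235).

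Xenobiotic metabolism split by gene. Of 30 genes, 4 rose, 4 fell and 22 did not pass, and adjusted over the list alone 4 rose and 6 fell. Cyp2b10 and Cyp3a11, classical targets of CAR and PXR, fell with log2 changes of -2.18 ± 0.28 and -0.67 ± 0.16, and microsomal epoxide hydrolase Ephx1 fell with -0.94 ± 0.10 (limma, adjusted p = 2.95e-07). Cyp1a2 and the sulfotransferase Sult1d1 rose by 0.47 ± 0.11 and 0.43 ± 0.10. The list did not pass and its median, above 0, differed in sign from its mean and test (fry in limma, adjusted p = 0.794). Of 28 genes of glutathione and oxidative stress response, 5 fell, none rose and 23 did not pass, the same counts as adjusted over the list alone (median -0.12, fry in limma, adjusted p = 0.000420). Camera in limma gave adjusted p = 0.0816 with an estimated correlation. The members that fell were glutathione transferases, among them Gsta2 (-0.58 ± 0.11), Gsta4 (-0.41 ± 0.08), Gsta1 (-0.52 ± 0.14) and Gstm4 (-0.52 ± 0.15).

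Among genes of microbial sensing and the acute phase, hepcidin, Hamp, which limits iron export, fell (log2 change -1.25 ± 0.18, all 14 germfree livers below the conventional mean), as did the flagellin receptor Tlr5 (-0.65 ± 0.17), its adaptor Myd88 (-0.41 ± 0.12) and the acute-phase protein Orm2 (-0.72 ± 0.21). Myd88 and Orm2 were lost in 12 and 8 of 30 fits that left out 1 liver. Of 36 tested genes of this list, 4 fell and 32 did not pass, adjusted over the list alone 1 rose and 4 fell, and the list did not pass (fry in limma, adjusted p = 0.0708). It passed downward in limma's camera with a preset correlation (adjusted p = 0.00468) but not with an estimated one (adjusted p = 0.425). Saa1 (-0.11), Saa2 (-0.56), Lbp (-0.12) and Hamp2 (0.42) did not pass. None of 27 interferon response genes passed, 4 were lower when adjusted over the list alone, and the list did not pass (fry in limma, adjusted p = 0.310).

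Of 12 tested markers of Kupffer cells and macrophages, 4 fell and 8 did not pass, and adjusted over the list alone 7 fell (median -0.40, fry in limma, adjusted p = 0.0130). The Kupffer list had adjusted p = 0.179 in limma's camera with an estimated correlation. With the replicate number as a block it had adjusted p = 0.0622 (fry in limma). The 4 were the Kupffer cell lectin Clec4f (-0.48 ± 0.10), the complement genes C1qa (-0.41 ± 0.09) and C1qc (-0.41 ± 0.13) and the iron exporter Slc40a1 (-0.58 ± 0.13); C1qc was lost in 21 of 30 fits that left out 1 liver. Of 5 tested adipocyte markers, 1 fell, 4 did not pass and adjusted over the list alone 2 fell (median -0.50, fry in limma, adjusted p = 0.0176), and with camera in limma adjusted p = 0.153 with an estimated correlation. The member that fell was the lipid droplet gene Plin4 (-0.69 ± 0.19). Plin4 did not pass with the replicate number as a block, on the same 28 arrays without the block, without a filter or after median scaling. It was also lost without the arrays with a mean signal under 160 and among the livers above 0 on the axis within groups.

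Of 14 hepatocyte secreted and core genes, 3 rose (Asgr2, Ahsg and Trf, by 0.32, 0.27 and 0.23), also adjusted over the list alone, and 11 did not pass (median 0.08, fry in limma, adjusted p = 3.90e-05). Trf was lost in 23 of 30 fits that left out 1 liver. The hepatocyte list had adjusted p = 0.114 with an estimated correlation (camera in limma). Under median scaling over the probes detected on all arrays it had adjusted p = 0.33 (fry in limma). Of 13 pericentral genes, 4 rose (Rnase4 by 0.50, Slc1a2 by 0.47, Gulo by 0.36 and Cyp1a2 by 0.47), 1 fell and 8 did not pass, and adjusted over the list alone 5 rose and 1 fell (median 0.23, fry in limma, adjusted p = 0.0130). The pericentral list had adjusted p = 0.291 in limma's camera with an estimated correlation. Of 12 periportal genes, 2 fell (Sox9, -0.83, and Ctsc, -0.51) and 10 did not pass, and adjusted over the list alone 1 rose and 3 fell (fry in limma, adjusted p = 0.235).

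Of 13 circadian clock genes, Rora alone rose, by 0.28 ± 0.08, also adjusted over the list alone but lost in 15 of 30 fits that left out 1 liver, and the list shifted up (median 0.18, fry in limma, adjusted p = 0.00308). With camera in limma this was adjusted p = 0.114 with an estimated correlation. None of 17 ribosomal protein genes passed, over all genes or over the list alone, while the list shifted up by a median of 0.11 (fry in limma, adjusted p = 0.0431). Camera in limma gave adjusted p = 0.425 with an estimated correlation, and the ribosomal list was lost in 13 of 30 fits that left out 1 liver. Among 6 tested pancreatic acinar genes, the elastase gene Cela2a alone rose, 2.82-fold (SE 0.18 on the log2 scale), with all 14 germfree livers above the conventional mean, and 1 rose adjusted over the list alone. The acinar list's median was 0.00 (fry in limma, adjusted p = 0.0402), and its test was not repeated without Cela2a. For these acinar genes limma's camera gave adjusted p = 0.273 with a preset and 0.514 with an estimated correlation, and the list was lost in 12 of 30 fits that left out 1 liver.

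**Figure D3:**
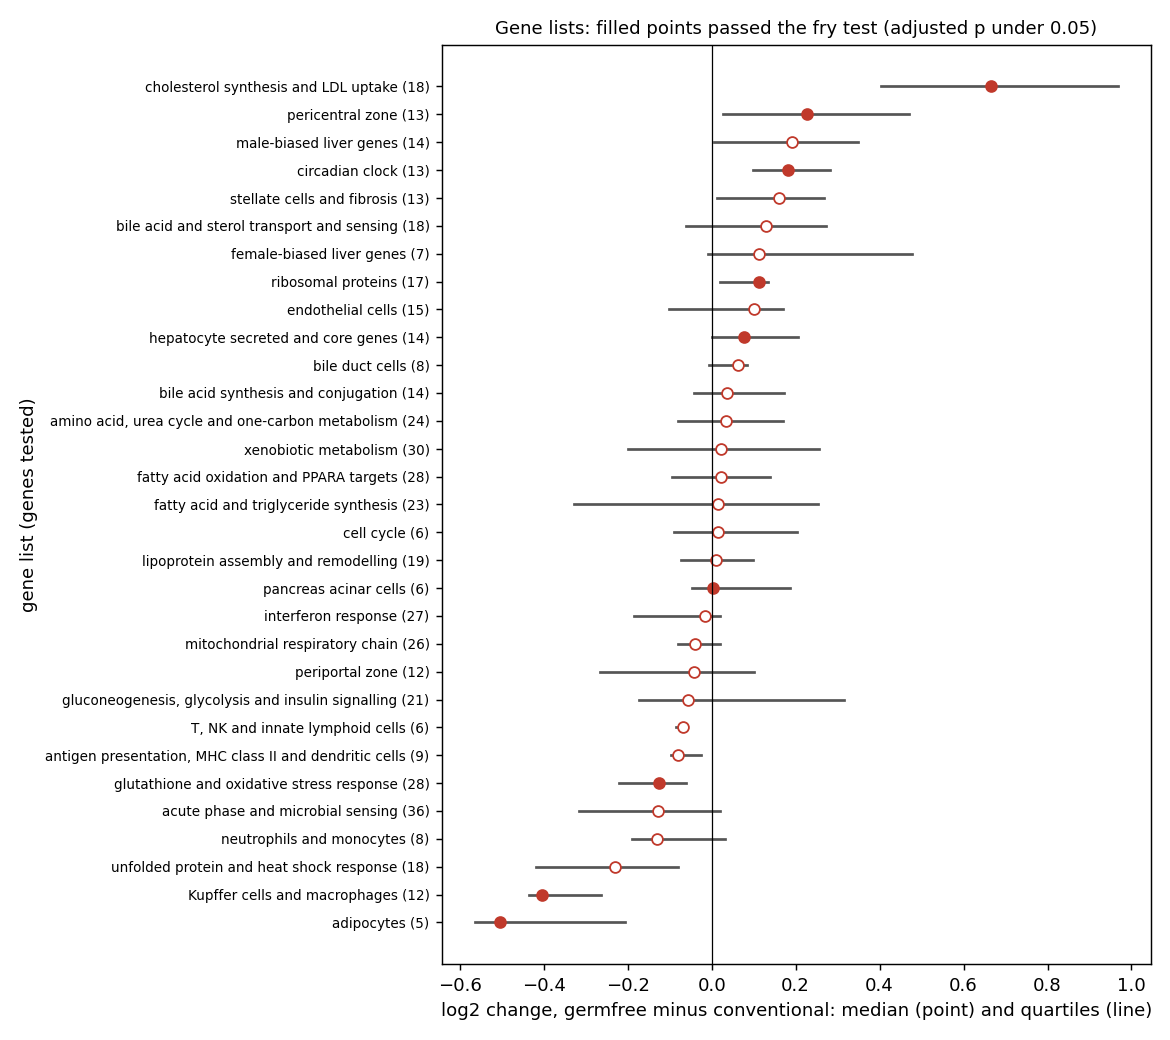
Median log2 change (point) and quartiles (line), germfree minus conventional, of each of 31 gene lists, with the number of genes tested in brackets. Filled points mark the 9 lists past the fry test, among which cholesterol synthesis had the largest median, 0.66.

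The other lists did not pass limma's fry test. T, NK and innate lymphoid markers had an adjusted p of 0.0542 in limma with 1 of 6 lower (Cd247, also adjusted over the list alone, detected in 12 of 16 conventional and 2 of 14 germfree livers and lost in 23 of 30 fits that left out 1 liver), and neutrophil and monocyte markers 0.291 with none of 8. Antigen presentation genes had an adjusted p of 0.398 in limma with none of 9. Endothelial markers had an adjusted p of 0.586 in limma with 1 of 15 higher (Stab2, 0.47), and stellate and fibrosis genes 0.0708 with 1 of 13 higher (Reln, 0.35; 4 adjusted over the list alone). Bile duct markers had an adjusted p of 0.794 in limma with 1 of 8 lower (Sox9), and their median, above 0, differed in sign from their mean and test. Male-biased genes had an adjusted p of 0.187 in limma with 2 of 14 higher (Susd4, 0.82, and C6, 0.37, the latter lost in 18 of 30 fits that left out 1 liver), and female-biased genes 0.291 with none of 7. Cell cycle genes had an adjusted p of 0.796 in limma with none of 6, and respiratory chain genes 0.0542 with none of 26. Unfolded protein and heat shock genes had an adjusted p of 0.274 in limma with 1 of 18 higher (Egr1, an immediate-early gene, 1.13 ± 0.29), while 2 rose and 5 fell adjusted over the list alone. With a preset correlation camera in limma called the stellate list higher and the unfolded protein list lower (adjusted p = 0.0483 and 0.0461), and with an estimated one neither (adjusted p = 0.425 and 0.582). Too few erythroid and B-cell genes were tested for a list test; of these Alas2 fell (-0.49 ± 0.12) and the transferrin receptor Tfrc rose (0.59 ± 0.17). Tfrc was lost without germfree liver 11 or 12 (limma, adjusted p = 0.0542 and 0.0525).

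Among the remaining genes with the largest rises were the zinc transporter Slc39a4 (1.42 ± 0.13), the mucosal repair peptide Tff3 (1.33 ± 0.33), Parp16 (1.27 ± 0.15) and the p53 target Trp53inp1 (1.09 ± 0.13). Large falls were seen for Wfdc2 (-1.73 ± 0.13, limma adjusted p = 1.89e-11), Csad, a taurine synthesis enzyme (-1.49 ± 0.18), the galectin Lgals1 (-1.37 ± 0.18), Aatk (-1.27 ± 0.28), the water channel Aqp8 (-1.20 ± 0.26), Tpm2 (-1.07 ± 0.19) and Id3 (-1.06 ± 0.13). Aqp8 was detected in 12 of 14 germfree livers, so the size of its fall is approximate. Obp2a fell and was detected in 14 of 16 conventional but 1 of 14 germfree livers. Most germfree values of Obp2a were thus not above background and the size of its fall is not given.

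After median scaling of the arrays, 69 genes (42 higher and 27 lower) and 1 list passed in limma. The livers also varied within each group along an axis that the labels do not name, with 15.1% of the variation within groups; limma called 34 genes among the 7 conventional and 5 germfree livers below 0 on that axis, 296 among the 9 and 9 above 0, and 751 with the axis as a covariate, which by construction leaves the changes themselves as they were.

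**Figure D4:**
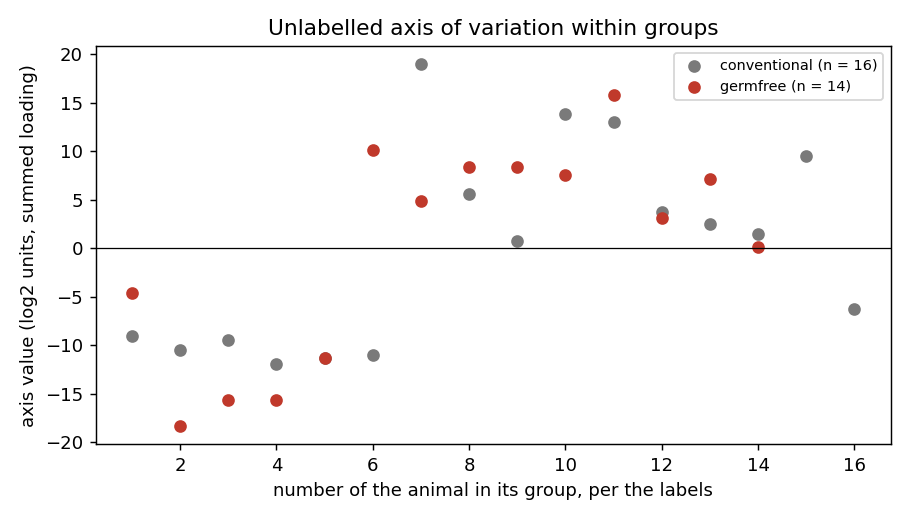
Value of each of 16 conventional and 14 germfree livers on the axis of variation within groups, against the replicate number in the sample title. Livers with numbers up to 5 lie below 0 in both groups, and the points of the 2 groups overlap at number 5.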

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

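Alternatives that concern the within-group axis, dim arrays, probes detected on all arrays and the 28 unblocked arrays were chosen after the data were seen. Under median scaling limma called 69 genes (42 higher, 27 lower) and 1 list in place of 590 (341, 249) and 9, and 49 of the 74 named genes past the threshold were lost. The median probe lies below detection on these arrays (61.8% of probes undetected), and after that scaling the median of the 6652 probes detected on all arrays still differed between arrays with an SD of 0.35, against 0.0080 after quantile normalization. Scaling to those 6652 probes gave 425 genes and 6 lists. It lost the hepatocyte, ribosomal and acinar lists (fry in limma, adjusted p = 0.33, 0.232 and 0.151). An adjusted p under 0.01 in limma left 264 genes (158, 106) and a change of at least 1.5-fold 113 (59, 54). Camera in limma with a preset correlation called 11 lists: 8 of the 9, without the acinar list, and the acute phase, stellate and unfolded protein lists. With an estimated correlation it left 1, cholesterol synthesis. Other lists gained were bile acid and sterol transport and sensing with the axis as a covariate (adjusted p in limma 0.0380), neutrophils and monocytes without a filter (0.0356), and T, NK and innate lymphoid cells with the detected share or the axis as a covariate (0.0453 and 0.0380). With 1 liver left out, the acute phase list was gained in 1 of 30 fits, stellate cells in 2, T, NK and innate lymphoid cells in 7 and the mitochondrial respiratory chain in 9. Among the 12 livers below 0 on the axis limma called 34 genes (17, 17) and 0 lists, and 964 genes had an unadjusted p under 0.05; among the 18 above 0 it called 296 (181, 115) and 3 lists. Both parts have fewer livers. All 590 genes had the same sign in both parts, but 100 random divisions of those sizes gave 585 to 590, so this says little. With the axis as a covariate limma called 751 genes and 11 lists, including all 590, but the axis has a mean of 0 in each group by construction, so it leaves each change as it was and only lowers the residual spread. Leaving out 1 liver at a time gave 519 to 609 genes, 292 to 364 higher, 210 to 274 lower and 7 to 12 lists. Under the other alternatives counts stayed within 1.5 times, from 430 without a filter to 661 with array weights, and without the 3 dim arrays (mean signal under 160) 443 genes and 8 lists passed. The cholesterol synthesis list passed in the main fit and in 47 other settings, with a highest adjusted p of 0.0231 (camera in limma, estimated correlation). In the remaining setting, below 0 on the axis, it did not pass (fry in limma, adjusted p = 0.103, median 0.74). Replicate numbers gave no clear pairing of the livers. Correlations of same-numbered livers ran from -0.18 to 0.37, 7 of 14 were over 0.1, and 4 of 28 arrays correlated best with their own number. Their median was 0.091, against -0.016 for livers of the 2 groups with different numbers, a difference that was not tested. With the replicate block limma called 497 genes (302, 195) and 7 lists, against 476 and 8 on the same 28 arrays without it. The block lost the Kupffer and ribosomal lists (fry in limma, adjusted p = 0.0622 and 0.081). Of the 74 named genes past the threshold the block lost 9: C1qc, Cd247, Cyp8b1, Gstm4, Plin4, Reln, Rora, Tfrc and Tlr5. On the same 28 arrays without the block 10 were lost. Without the block the ribosomal list was lost (fry in limma, adjusted p = 0.0556). The chip as a block was not run, since no chip is given in the sources used here.

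Of the 74 named genes past the threshold, 64 stayed past it whichever liver was left out, 12 in all settings, and none changed sign; the other 10 were Abcg8, C1qc, C6, Cd247, Cyp4a10, Myd88, Orm2, Rora, Tfrc and Trf, lost in 2 to 23 of 30 such fits (highest adjusted p in limma 0.0899). Signs changed for 15 named genes and 9 lists, none past the threshold before or after, and the cause was not tested. Below 0 on the axis the log2 changes were Muc1 0.032, Cd3d 0.15, Cd74 0.11, Tyms 0.11, H2-Aa 0.053, Cyp2f2 0.011, Abcb11 0.023, Rrm2 0.0034 and Apoa4 0.28, and above 0 Ms4a1 0.057, Reg1 0.017, Siglech 0.020 and Saa1 0.047. Without dim arrays Ms4a1 had 0.017 and Saa1 0.0024. Ms4a1 had 0.025 under median scaling, 0.021 under cyclic loess and 0.010 under scaling to probes detected on all arrays, and Acot3 had -0.029 with array weights. List directions turned, with these adjusted p values in limma. With the replicate block they were 0.800 for fatty acid synthesis and 0.985 for xenobiotic metabolism, and without it on the 28 arrays 0.979 for fatty acid synthesis. Below 0 on the axis they were 0.957 for fatty acid synthesis, 0.901 for fatty acid oxidation, 0.943 for xenobiotic metabolism, 0.486 for interferon response, 0.723 for endothelial cells and 0.901 for periportal genes, and above 0 0.391 for cell cycle. Median scaling gave 0.928 for fatty acid oxidation and 0.900 for bile duct cells, and cyclic loess 0.847 for bile duct cells. Without dim arrays they were 0.801 for bile duct cells and 0.797 for cell cycle, and without a filter 0.866 for cell cycle. With 1 liver left out the log2 changes ran from -0.050 to 0.24 for Acot3, -0.026 to 0.097 for Slc10a1 and -0.040 to 0.023 for Ms4a1. The adjusted p in limma ran from 0.602 to 0.997 for fatty acid synthesis, 0.699 to 0.985 for fatty acid oxidation, 0.548 to 0.966 for gluconeogenesis, 0.443 to 0.946 for xenobiotic metabolism, 0.452 to 0.980 for bile duct cells and 0.487 to 0.942 for cell cycle.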

Other observations

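Tests of array brightness, of the replicate numbers, of fasting, of the axis as a source of the cholesterol result, and of Cela2a were chosen after the result was seen. Chance alone was unlikely to give the number of genes and of lists. Of 100 splits of the 30 livers into 16 and 14, 1, the real one, gave 590 genes or more. The highest of the others gave 129. For lists, 1 of 100 gave 9 or more and the highest of the others gave 1. The real split is counted among the 100, so a lower share was not possible. The splits also take the livers as exchangeable, although they varied along an axis that the labels do not name.

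Livers varied within both groups along an axis that the labels do not name. Per SD of the axis, the 3 largest changes each way among genes with a symbol were -1.13 for Fbxw5, -1.05 for Fgg and -0.89 for Bhmt, and 1.06 for Psmc1, 0.60 for Lcn2 and 0.54 for Saa3 on the log2 scale, a choice made after the values were seen. Along it 5 of 31 lists went down, bile acid and sterol transport, xenobiotic metabolism, pericentral genes, bile acid synthesis and periportal genes (fry in limma, adjusted p = 0.000909, 0.00116, 0.00391, 0.00611 and 0.0122). Ribosomal proteins went up (fry in limma, adjusted p = 0.0122). The axis was computed from these same genes, so genes that make it up follow it by construction. These p values therefore describe the axis and are no independent test.

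The axis correlated with the replicate numbers in the sample titles in both groups (permutation tests, two-sided). Whether these numbers follow any order of animals or processing is not given. A different number that heads each array in the deposited signals was not tested. Spearman's rho was 0.541 in conventional (permutation p = 0.0327) and 0.547 in germfree livers (permutation p = 0.0462). The values stepped up and did not rise steadily with the number. Conventional livers 1 to 6 and germfree livers 1 to 5 lay below 0, and all later ones but conventional 16 lay above. Pearson's r was 0.516 (permutation p = 0.0419) and 0.680 (permutation p = 0.00875), and without the 2 livers with the most extreme numbers 0.624 and 0.800; the 4 p values adjusted together were 0.0462, 0.0462, 0.0462 and 0.0350, the last for Pearson's r in germfree livers. The mean of the acute-phase list accounted for 0.0724 of the variance of the axis (bootstrap interval 0.00031 to 0.364) and the list did not pass along it (fry in limma, adjusted p = 0.253), but 11 of its 36 members went up and 3 down, so the mean does not decide and inflammation stays open. Brightness and detection accounted for 0.268 (bootstrap interval 0.0365 to 0.583), which leaves them open too. Livers handled in batches may be the source, but no batch was given in the sources used here.

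Cholesterol synthesis rose as a list in germfree liver. A shorter effective fast in germfree mice would lower fasting-induced genes. Of 16 such genes listed, the 10 tested had a median log2 change of 0.40 and 3 passed, none lower. All 10 had a change above 0 (fry in limma, unadjusted p = 8.0e-05). The fasting genes thus shifted up as a set, and a longer effective fast in germfree mice was not tested. The cholesterol synthesis list moved little along the axis. The upper bound of its slope times the whole range of the axis (3.56 SD) gave 0.43. That was below the lower bound of the list's mean change, 0.48. The axis has a mean of 0 in each group by construction, so a larger shift between the groups along it was not bounded. The criterion was also set with these bounds in view, after earlier tests of the axis had proved void. The axis as the source thus stays open. Under 5 other background corrections and scalings the median was at least 0.49. A shorter fast and the scalings tried thus did not account for the rise. The fasting genes bear on this only if microbial status does not itself change them. A batch between the groups that the labels do not give could not be told apart from microbial status. An effect of the missing microbiota on hepatic sterol synthesis may be a hypothesis. Sterol levels and absorption were not measured here.

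Cela2a rose 2.82-fold in germfree liver. Pancreas carried over at dissection would bring the other acinar genes, but over the 16 others on the array the median log2 change was -0.016 (quartiles -0.051 and 0.023), and 8 were detected in no germfree liver. Cela1 transcripts binding the Cela2a probe would need Cela1 to rise as much, while the upper bound of its change was 0.50 and the lower bound for Cela2a was 1.13. Expression in liver cells may account for the signal, a hypothesis that these arrays do not test.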
